A study of Mus musculus with 4 samples.

How the data were processed

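Transcripts were measured in wells of 96-well plates, 2 plates of morula and 2 plates of blastocyst wells, with the control morpholino in the even and the NKX1-2 morpholino in the odd wells, per the labels. The deposited values are counts per gene and well barcode, whole numbers without normalization. A table deposited with them gives the morpholino of each of the 96 barcodes and is the same for every plate. The labels' protocols describe lysis with a detergent, polyA capture and an Illumina TruSeq library, while the labels' descriptions name 10x Genomics. TopHat2 and the builds GRCm38 and mm10 are named per the submitters' processing notes, without a version or a role. The counting tool, the use of strand and whether reads or molecules were counted are not given in the sources used here. Whether a well held a single cell or more is not given either, beyond the label of a single cell source.

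The files hold 55453 genes, of which 54510 (98.3%) were matched by symbol to the GENCODE M21 annotation of GRCm38. In both morula plates, 344 neighbouring genes of the files, from U2af1 to V1rg10, have no count, while they hold 1.68% and 1.67% of the counts of the blastocyst plates. These genes were left out of every fit that holds morula wells. In a fit of the blastocyst plates alone, 3 of 196 of them passed, 1 higher and 2 lower.

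Wells with at least 2000 detected genes were kept, 368 of 384, and 16 were left out. Counts were summed per plate and morpholino, which gave 8 sums of 1084312 to 2398605 counts. Genes with low counts were removed with filterByExpr, and sums were normalised by TMM (edgeR 4.0.16, limma 3.58.1, R 4.3.3). Log2 fold changes per plate were taken from log CPM with a prior count of 2, which shrinks them at low counts. They are thus not on the scale of the log2 fold changes of the fit. The effect of the morpholino was tested in the morula, in the blastocyst, on average and as the difference between the stages, in 1 robust quasi-likelihood fit of all 8 sums with the plate as a block. The stages were compared in separate fits of the 4 control sums and of the 4 NKX1-2 sums. Benjamini-Hochberg adjusted p-values under 0.05 passed. The plate is the block because both sums of a plate share it by design. Sums of the same plate had deviations that correlated at 0.257 in the morula and at -0.000704 in the blastocyst.

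The models were tested on simulated data with 200 changed genes. For the morula comparison, on 10560 genes, 85% of the genes changed 2-fold and 99% of those changed 4-fold were recovered, for the blastocyst, on 10570 genes, 72% and 100%, and for the average effect, on 10530 genes, 92% and 99%. For the difference between stages, on 10540 genes, 39% and 94% were recovered, and for the stages in control wells, on 9337 genes, 77% and 99%. No recovered gene had the wrong sign, and 16, 18, 30, 5 and 6 unchanged genes were called. At most 200 calls per comparison could be true. For the morula, the blastocyst and the average effect, unchanged genes thus made up a share of the calls above 0.05. The threshold was too lenient there in the simulation. The percentages refer to the changed genes, and recovery was not given by expression level.

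A set of 33 gene lists was tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry, where at least 5 members were tested. With an estimated correlation, camera has few degrees of freedom at this number of sums, so hardly any list could pass. Named genes were chosen by a rule. It took the 10 genes with the largest change in each direction (5 for the difference between stages) among those that passed, moved the same way in every plate concerned, reached 20 CPM in a group and had a gene name. Where fewer passed, the genes with the smallest p filled the number. It added Nkx1-2, up to 4 members of each list with a call, and 16 lineage, nucleolar, Wnt and p53 genes. The design, the lists, the rule and most alternatives were fixed before the data were examined. A fold against a group with 0 counts was computed against a floor of 3 counts over the group, and a ratio with 1 to 3 counts was given a 95% exact interval.

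Blastocyst wells were clustered with scanpy 1.11.5 and leidenalg 0.10.2 (2000 variable genes, 15 principal components, 15 neighbours, resolution 1.0, and also 0.5 and 1.5). A cluster was named from at least 3 fixed markers among its top 10 genes. Doublets were not called. Sex classes of wells were taken from Xist and from Eif2s3y, Ddx3y and Kdm5d. Shared sequence was measured as the percent of 31-base stretches of a gene's transcripts that occur in another gene. Figures were drawn with matplotlib 3.10.9, and other values were computed with Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.

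The alternatives fixed in advance were RLE size factors, DESeq2 1.42.0, no filter on low counts, every well, wells with at least 4000 genes, deep wells thinned to the plate median, limma voom, no plate block and each plate left out. Settings added later were the highest well of each gene left out, female wells, autosomes and protein-coding genes, and, for the gene lists, every well and thinned wells. Shares of cell types were not compared, since most clusters could not be named. Values of some named genes are not reported here.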

Results

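Transcripts were counted per well, from a source labelled as single cells, in mouse embryos injected with a morpholino, an antisense oligonucleotide that blocks the translation or the splicing of its target RNA. One morpholino targeted NKX1-2, a homeobox transcription factor, and the other was a control. Wells were taken at the morula stage, a compact ball of cells, and at the blastocyst stage, when an outer trophectoderm surrounds the inner cell mass. Each stage had 2 plates of 96 wells, and every plate held 48 control wells and 48 NKX1-2 wells. The plates held 4529880 and 4481781 counts at the morula stage, and 2505234 and 3165841 counts at the blastocyst stage. After wells with fewer than 2000 detected genes were left out, 368 of 384 wells remained, and counts were summed per plate and morpholino. The control sums of the morula plates held 2157307 and 2081917 counts, and the NKX1-2 sums 2372573 and 2398605. The control sums of the blastocyst plates held 1084312 and 1461141 counts, and the NKX1-2 sums 1412197 and 1685358. The plate was the replicate, with n = 2 per stage, because no label ties wells to embryos. Adjusted p-values therefore measure the spread between these plates, and exact intervals and floors cover counting error only.

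The targeted gene, Nkx1-2 (ENSMUSG00000048528), lies on the minus strand of chromosome 7 at 132594878 to 132599637 in the mouse build GRCm38. It had 0 counts in all 384 wells, which allows a level of up to 0.204 CPM over all wells together. Per plate and morpholino, the level that 0 counts allow lay between 1.25 and 2.75 CPM. Its RNA was not detectable at this depth in control or NKX1-2 wells, so these counts do not check the labels. A morpholino need not lower the RNA of its target.

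The first comparison asked which genes differed between NKX1-2 and control wells of the morula. Gata3, a trophectoderm transcription factor, rose from 7.38 ± 2.70 to 27.6 ± 6.56 CPM (SD, n = 2 plates), a log2 fold change of 1.87 (SE 0.35, adjusted p = 0.0278, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). Nup214, a nuclear pore protein, rose by 1.78 (SE 0.19) on the log2 scale, and Sdc4, a cell surface heparan sulfate proteoglycan, by 1.65 (SE 0.29). Acyp1, an acylphosphatase, showed the largest drop, from 57.1 ± 11.5 to 5.98 ± 1.30 CPM (log2 fold change -3.23, SE 0.30). Hnrnph3 and Hnrnpa2b1, which encode RNA-binding proteins, fell by 1.53 (SE 0.19) and by 1.07 (SE 0.14) on the log2 scale. In total, 60 of 10873 genes passed an adjusted p of 0.05 by edgeR, 30 higher and 30 lower. Wells with Xist and without Y-linked counts made up 10 of 48 NKX1-2 wells against 25 of 48 control wells in morula replicate 1, and 23 of 47 against 27 of 48 in replicate 2. Among the other genes that rose were Prpf38a (log2 fold change 1.38), a splicing factor, the ribosome biogenesis factor Pwp1 and the transcription factor Elf1 (1.51). Anxa2 (-1.59), a membrane-binding annexin, the Mediator subunit Med21 (-1.50) and the proteasome assembly chaperone Psmg3 (-1.27) fell. In the p53 target list, 1 of 32 tested genes rose, Pmaip1 (1.30, SE 0.26), a pro-apoptotic BH3-only protein, and 4 genes were higher when adjusted over the list alone. Cdkn1a, a cell cycle inhibitor, had a log2 fold change of 0.56 (adjusted p = 0.128) and Btg2 one of 1.67 (adjusted p = 0.178), and neither passed. In the trophectoderm list, 1 of 24 genes rose, Gata3, and 2 were higher when adjusted over the list alone, while Fabp3 had a log2 fold change of 0.86 (adjusted p = 0.0521). The translation initiation factor list had 2 of 57 genes lower, Eif3e (-0.69, SE 0.13) and the pseudogene Eif3s6-ps2 (-1.69, SE 0.34), which shares sequence with other genes and is uncertain. The cytosolic ribosomal protein list lay lower as a group by camera (median log2 fold change -0.09, adjusted p = 0.000701), with 20 of 89 genes above 0 and 69 below. Adjusted p = 0.953 with an estimated correlation for this list, and 0 of its genes passed by themselves by edgeR. The list did not pass in female wells or in at least 1 fit with a plate left out. Some of its genes had far lower levels in morula than in blastocyst control wells, such as Rpl3 (204 against 2481 CPM) and Rpl12 (125 against 2545 CPM). Rplp0 was close to its blastocyst level (3615 against 4020 CPM). The counting of this list in the morula is thus uncertain. The other 32 lists did not pass. Of the genes named in every comparison, 13 did not pass, among them Cdkn1a, Cdx2, Nanog, Sox2, Pou5f1, Gata6, Fbl, Ncl and Npm1, with log2 fold changes from -0.31 to 0.93 (lowest adjusted p = 0.128). The count of 60 fell to 15 with DESeq2, to 34 without the plate as a block, and to 17 or 13 without morula replicate 1 or 2, and rose to 833 or 838 without blastocyst replicate 1 or 2 and to 834 with the morula plates alone. The value of Gata3 was 1.33 without morula replicate 2 (adjusted p = 0.531) and that of Sdc4 0.99 without morula replicate 1 (adjusted p = 0.587), and Olfr1109, 1.37 in all wells, was at -1.08 when its highest well was left out. Pmaip1 lay between 0.10, in female wells, and 1.42 over 16 alternative settings and did not pass in 7 of them, among them DESeq2 and each morula replicate left out.

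The same question was asked of the blastocyst wells. Acyp1 (log2 fold change -2.66, SE 0.43) and Med21 (-1.93, SE 0.22) again fell, and Nup214 (1.33, SE 0.22) again rose. Smim24, a small membrane protein, fell from 20.8 to 2.12 CPM (-3.25, SE 0.51), and Rrm1, the large subunit of ribonucleotide reductase, fell by 1.28 on the log2 scale (SE 0.18). Tmsb4x, an actin-sequestering peptide encoded on chromosome X, rose from 2.75 to 34.1 CPM (3.66, SE 0.49), and Romo1, a mitochondrial inner membrane protein, rose by 1.75 (SE 0.24). In total, 79 of 10873 genes passed by edgeR, 42 higher and 37 lower. Of these, 10 of the higher and 0 of the lower genes lay on chromosome X. The X-linked genes Magea8 (3.26) and Magea5 (2.14) were among them, and both share over 50% of their sequence stretches with other genes, so their reads are uncertain. Wells with Xist and without Y-linked counts made up 35 of 47 NKX1-2 wells against 15 of 43 control wells in blastocyst replicate 1, and 20 of 44 against 6 of 43 in replicate 2. Both kinds of counts were found in 7 of 47 NKX1-2 and 8 of 43 control wells of replicate 1. In replicate 2 they were found in 22 of 44 and 19 of 43 wells, so sex classes are uncertain there. The p53 target list had 1 of 32 genes lower, Tigar (-0.66, SE 0.14), a regulator of glycolysis, and 4 lower when adjusted over the list alone. The stress gene Ddit4 (-1.52, SE 0.28) and the serine synthesis enzyme Phgdh (-0.66, SE 0.13) were the 2 of 27 integrated stress response genes that fell, and 4 were lower when adjusted over the list alone. Phgdh shares 55.9% of its stretches with other genes, and Tyms, Rpl3 and Rpl12 have annotated pseudogenes, so their reads are uncertain too. In the S phase list, Cdc45 (1.14, SE 0.22), a replication fork helicase component, and Tyms (0.63, SE 0.13), thymidylate synthase, rose and Rrm1 fell, out of 48 tested genes. By camera, the nuclear oxidative phosphorylation list lay higher (median 0.08, adjusted p = 0.0148), with 2 of 77 genes that rose, Cox8a (0.97, SE 0.15) and the X-linked Ndufb11 (0.70, SE 0.15), and 9 higher and 2 lower when adjusted over the list alone. Adjusted p = 0.839 for this list with an estimated correlation, which was 0.261 against the preset 0.01, and adjusted p = 0.636 by fry. The ribosome biogenesis list also lay higher (median 0.10, adjusted p = 0.0166, adjusted p = 0.839 with an estimated correlation), with 1 of 123 genes that rose, Pwp1 (0.98, SE 0.20). The proteasome list (median 0.09, adjusted p = 0.0148) had 0 of 35 and the imprinted gene list (median 0.46, adjusted p = 0.0166) 1 of 14 genes that rose by edgeR, the amino acid transporter Slc38a4 (1.69, SE 0.37). The cytosolic ribosomal protein list lay lower (median -0.07, adjusted p = 0.0148), with 2 of 89 genes that fell, Rpl3 (-0.56, SE 0.10) and Rpl12 (-0.48, SE 0.10), as did the Hippo and YAP list (median -0.48, adjusted p = 0.0148), with 0 of 16 by edgeR. Adjusted p = 0.799 with an estimated correlation for each of these 4 lists, and the other 27 lists did not pass. Fewer lists passed by camera in female wells. Of the genes named in every comparison, 14 did not pass, Gata3, Cdx2, Cdkn1a and Mdm2 included, with log2 fold changes from -0.33 to 0.55 (lowest adjusted p = 0.312). Zbed3 had 62 counts in NKX1-2 wells and 1 in control wells, a ratio of 51.0 with a 95% exact interval of 8.81 to 2044, and it did not pass when its highest well was left out (adjusted p = 0.260). The count of 79 fell to 21 with DESeq2 and to 43 without the plate as a block, and rose to 565 or 635 without blastocyst replicate 1 or 2 and to 123 with the blastocyst plates alone, while Ddit4 was at -0.80 (adjusted p = 0.139) without blastocyst replicate 1. Tigar, Ndufb11 and Slc38a4 each did not pass in 7 of the alternative settings, among them DESeq2 and no plate block.

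**Figure D1:**
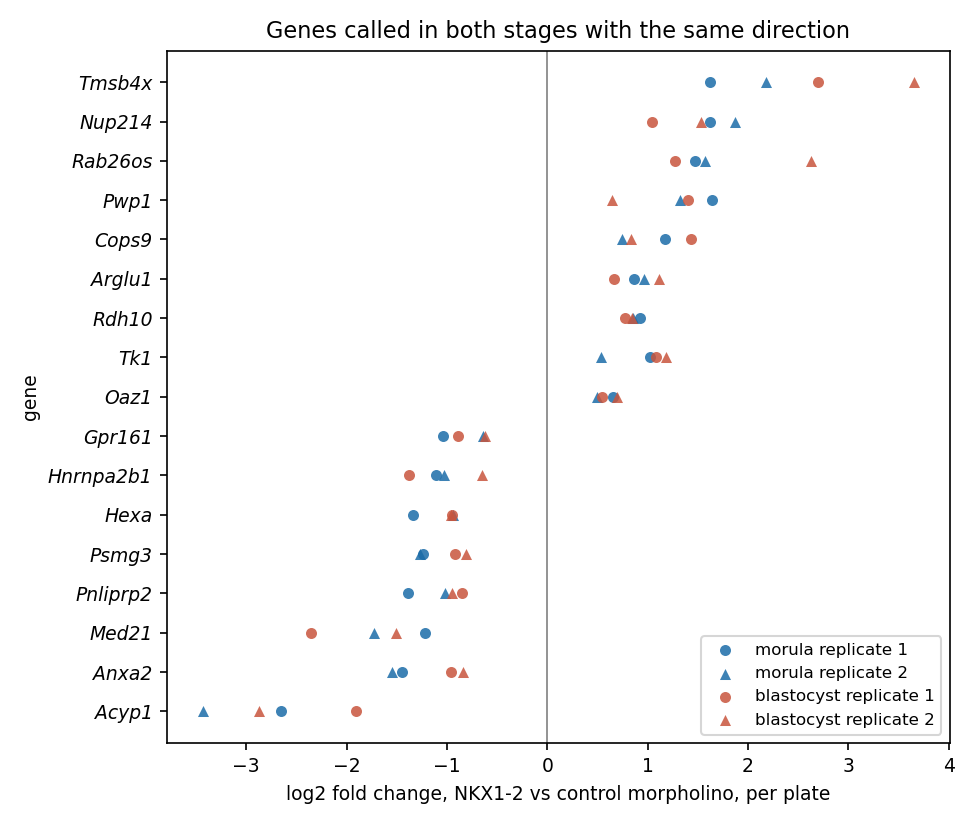
Log2 fold change of NKX1-2 against control wells (x axis) for the 17 genes that passed in both stages with the same direction (y axis), with 1 point per plate. Values per plate used a prior count of 2. All 9 higher genes lie above 0 and all 8 lower genes below 0 in each of the 4 plates, and Acyp1 lies between -3.43 and -1.90.

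The overlap of both stages was then tested. Of the genes that rose, 9 were shared between morula and blastocyst, against 0.116 from independent lists (Fisher's exact test, one-sided, p = 1.03e-15), and of those that fell 8 were shared, against 0.102 (p = 4.44e-14). The shared genes included Acyp1, Med21, Hnrnpa2b1, Psmg3 and Anxa2, which fell, and Nup214, Pwp1, Rab26os and Tmsb4x, which rose. Rab26os is annotated as an antisense RNA, and 0% of its exonic length overlapped exons on the opposite strand. The direction was the same in the other stage for 52 of the 60 morula genes and 70 of the 79 blastocyst genes, against 59.6% of all tested genes.

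The average effect over both stages used all 4 plates. Tmsb4x (log2 fold change 3.07, SE 0.36), Rab26os (1.82, SE 0.20) and Nup214 (1.55, SE 0.15) rose, and Acyp1 (-2.94, SE 0.26), Smim24 (-2.23, SE 0.32) and Med21 (-1.71, SE 0.15) fell. In total, 315 of 10873 genes passed by edgeR, 170 higher and 145 lower, and 300 of them had the same direction in all 4 plates. The median size was 0.736 on the log2 scale, and 85 genes changed by more than 1 on that scale, 49 higher and 36 lower. Among the other genes that rose were Gata3 (1.21, SE 0.22), the interferon-induced Oasl2 (1.40, SE 0.28) and the MHC class II gene H2-Ab1 (1.64, SE 0.36). Arrb2 (-1.44, SE 0.28), a beta-arrestin, Galt (-1.36, SE 0.22), a galactose enzyme, and Snx17 (-1.27, SE 0.25), a sorting nexin, fell. Meg3, an imprinted noncoding RNA, had 0 counts in control wells and 30 in NKX1-2 wells, at least 8.62-fold higher against a floor of 3 counts over the group. The ribosome biogenesis list had 6 of 123 genes higher, such as Pwp1 (1.24, SE 0.13), Nmd3 (0.54, SE 0.12) and Wdr74 (0.40, SE 0.09), and 1 lower, Rrp1b (-0.84, SE 0.17), but did not pass as a group (camera, adjusted p = 0.0542). Adjusted over the list alone, 8 of its genes were higher and 1 lower. In the RNA polymerase I list, Polr1a (-0.95, SE 0.21), the largest subunit, was the 1 of 20 genes that fell. Tcf7l2 (-0.98, SE 0.23), a transcription factor of the Wnt pathway, was the 1 of 14 Wnt target genes and the 1 of 26 Wnt pathway genes that fell. In the S phase list, Tyms (0.60, SE 0.09), Cdc45 (0.88, SE 0.14) and Rfc4 (0.98, SE 0.19) rose and Rrm1 (-1.04, SE 0.14) fell, out of 48. The cytosolic ribosomal protein list lay lower by camera (median -0.07, adjusted p = 0.000490, adjusted p = 0.936 with an estimated correlation). This list did not pass in female wells or in at least 1 fit with a plate left out. In it, 4 of 89 genes fell, such as Rps24 (-0.25, SE 0.06) and Rpl3 (-0.33, SE 0.08), and 7 were lower and 1 higher when adjusted over the list alone. Both genes have annotated pseudogenes, and the counting of this list in the morula is uncertain. The other 32 lists did not pass by camera, and the fry test called 1 list, the 7 tested interferon response genes (adjusted p = 0.0404, higher), of which Oasl2 passed by itself. The count of 315 fell to 60 with DESeq2, to 185 without the plate as a block, and to 92 or 128 without morula replicate 1 or 2, and rose to 1008 or 1071 without blastocyst replicate 1 or 2. Tcf7l2 lay between -1.29 and -0.70 over 15 alternative settings and did not pass in 7 of them, and Oasl2 was at 0.15 in female wells.

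**Figure D2:**
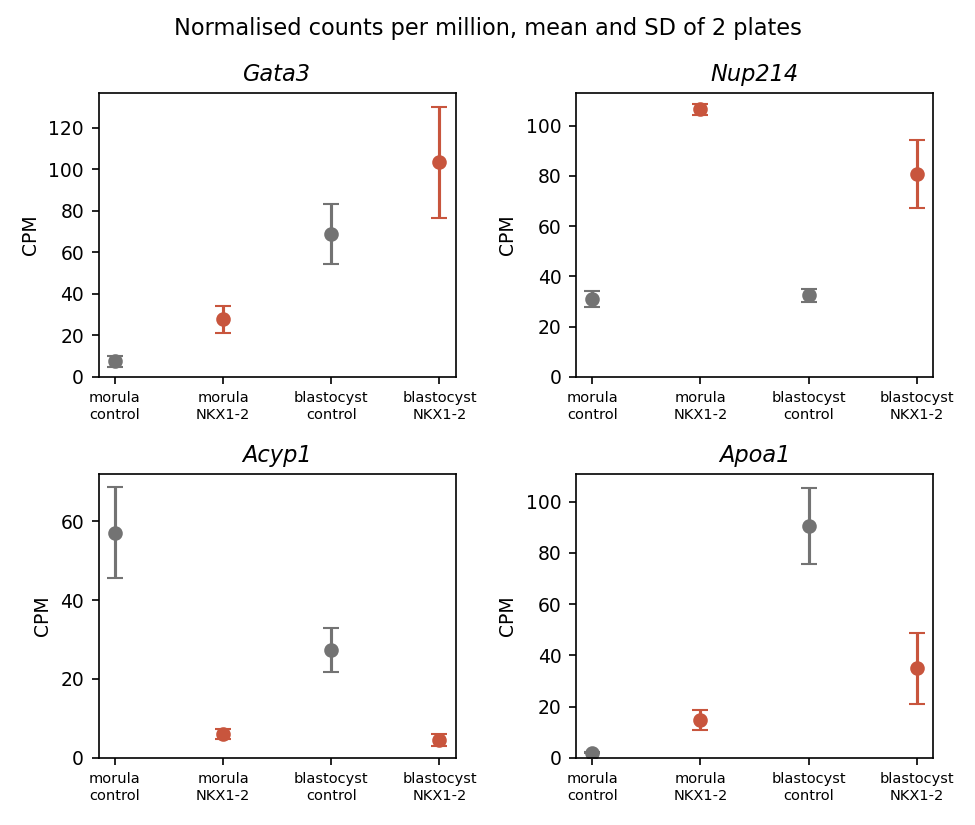
Normalised counts (CPM) of Gata3, Nup214, Acyp1 and Apoa1 (y axes, starting at 0) per stage and morpholino (x axes), with points for the mean and bars for the SD of 2 plates. Apoa1 was higher with the NKX1-2 morpholino in morula wells and lower in blastocyst wells.

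The next comparison asked whether the effect of the morpholino differed between the stages. Apoa1, which encodes the main protein of high-density lipoprotein, rose from 1.97 to 14.7 CPM in morula wells and fell from 90.5 to 34.9 CPM in blastocyst wells. The effects on Apoa1 differed by -4.22 on the log2 scale (SE 0.48, adjusted p = 0.00146, edgeR). The log2 fold change of Apoa1 was 2.02 and 2.67 in the morula plates and -1.63 and -1.15 in the blastocyst plates. The unnamed gene model 4930500L23Rik, chosen after its values were seen, differed by 2.25 (SE 0.34), and these were the 2 genes that passed by edgeR. The effect on the p53 target list differed between the stages, with a median difference of -0.34 (camera, adjusted p = 0.000133, adjusted p = 0.930 with an estimated correlation) and 5 of 32 genes lower when adjusted over the list alone. The list itself passed in neither stage (adjusted p = 0.103 in the morula and 0.0572 in the blastocyst). Pmaip1 had a difference of -1.57 (adjusted p = 0.233), with log2 fold changes of 1.31 and 1.10 in the morula plates and of -0.25 and -0.28 in the blastocyst plates. The nuclear oxidative phosphorylation list had a median difference of 0.19 (camera, adjusted p = 2.63e-06), with 64 of 77 genes above 0, and the proteasome list one of 0.14 (adjusted p = 0.0254). Adjusted p = 0.930 with an estimated correlation for all 3 lists, and the other 30 did not pass. The count of 2 fell to 1 with DESeq2 and without the plate as a block, and rose to 252 or 246 without blastocyst replicate 1 or 2. In female wells alone, the difference of Apoa1 was -5.65 but did not pass, and the p53 target and proteasome lists did not pass. No gene with a higher effect in the blastocyst passed with DESeq2, voom, every well, thinned wells, female wells or without the plate as a block, so that 4930500L23Rik was lost there. It was also lost without morula replicate 2.

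**Figure D3:**
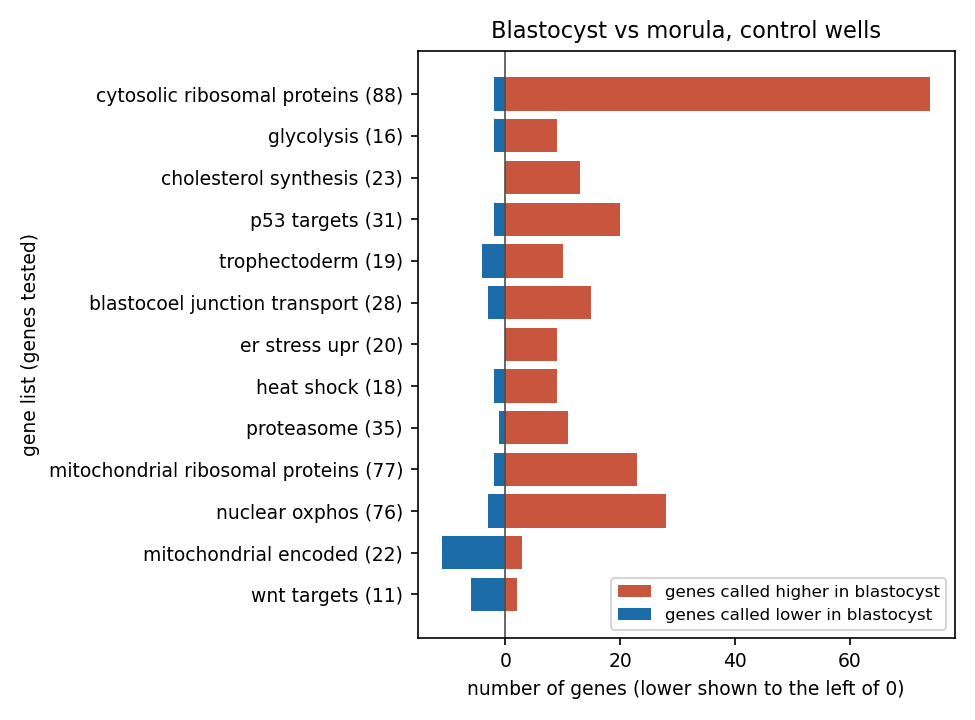
Number of genes called higher (right of 0) and lower (left of 0) in blastocyst than in morula control wells (x axis) for the 13 gene lists that passed by camera (y axis, with the genes tested in brackets). The cytosolic ribosomal protein list had 74 of 88 genes higher and 2 lower. Most genes of this list have a pseudogene named after them, so stage and counting cannot be separated in them.

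Blastocyst and morula were compared within control wells. Trophectoderm genes were higher in the blastocyst, with Gata3 at a log2 fold change of 3.22 (SE 0.34), the endocytic receptor Lrp2 at 5.80 (SE 0.39), the adaptor Dab2 at 3.15 (SE 0.26) and the keratin Krt18 at 2.63 (SE 0.26). In that list, 10 of 19 genes rose and 4 fell (camera, adjusted p = 0.0274, adjusted p = 0.626 with an estimated correlation). Cdx2, a trophectoderm transcription factor, rose from 2.67 to 11.9 CPM (2.13, SE 0.56). In the list of inner cell mass and epiblast genes, 6 of 21 rose and 12 fell, and it did not pass as a group (adjusted p = 0.318). Tfcp2l1 (2.04, SE 0.21), Dnmt3l (1.49, SE 0.23) and Nanog (1.19, SE 0.26) rose, while Klf2 (-2.80, SE 0.18), Spic (-2.27, SE 0.18) and Tdgf1 (-2.36, SE 0.23) fell. Of these, Dnmt3l, Nanog and Tdgf1 have annotated pseudogenes. In total, 3993 of 9577 genes passed by edgeR, 1921 higher and 2072 lower. In the p53 target list, 20 of 31 genes rose and 2 fell (adjusted p = 7.38e-05, adjusted p = 0.510 with an estimated correlation), with Pmaip1 at 3.42 (SE 0.29) and Mdm2 at 2.33 (SE 0.27). The endoplasmic reticulum stress list had 9 of 20 genes higher, such as Hsp90b1 (2.81, SE 0.20) and Hspa5 (1.78, SE 0.20), with adjusted p = 0.00243, and adjusted p = 0.510 with an estimated correlation. The list of junction and transport genes of the blastocoel had 15 of 28 higher and 3 lower, with Epcam at 2.11 (SE 0.23) and Ctnnb1 at 2.41 (SE 0.28) but Cldn4 at -2.13 (SE 0.27). Its adjusted p = 0.0210, and adjusted p = 0.513 with an estimated correlation. In the Wnt target list, 6 of 11 genes fell, such as Myc (-3.22, SE 0.44) and Tcf7l2 (-2.28, SE 0.30), and 2 rose (adjusted p = 0.0419, adjusted p = 0.641 with an estimated correlation). In the Wnt pathway list, 11 of 25 genes fell and 1, Ctnnb1, rose. This list did not pass as a group by camera (adjusted p = 0.0922) but lay lower by fry (adjusted p = 0.0344). The heat shock, glycolysis, proteasome, nuclear oxidative phosphorylation and both ribosomal protein lists also lay higher and the mitochondrially encoded list lower. Of the 33 lists, 13 passed by camera. The lowest adjusted p was 0.231 with an estimated correlation, so 0 of the 13 lists passed that test, against 16 at an unadjusted camera p under 0.05 and 12 by fry. With so few sums the test with an estimated correlation has few degrees of freedom, so a failure in it says little about a list. Adjusted over the list alone, the trophectoderm counts were 10 and 4, the p53 counts 20 and 2, and the Wnt target counts 2 and 6. Cdx2 lay between 1.48 and 3.11 over 15 alternative settings and did not pass with DESeq2 or without morula replicate 1.

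Some of the largest stage differences lay in genes whose reads can be shared or overlap another gene. Of 177 protein-coding genes that were called and more than 8-fold higher, 36 had a pseudogene named after them among the genes of the files. Copies under other names were not counted. Of the 177, 22 overlapped exons on the opposite strand over at least 50% of their exonic length. Snora73b had 0 counts in morula wells and was at least 1023-fold higher in blastocyst wells against a floor of 3 counts over the group, and the integrin-linked kinase gene Ilk at least 120-fold higher. Of the exonic length of Snora73b, 100% overlapped exons on the opposite strand, and of that of Ilk 89.7%. Med10, 8.73 higher on the log2 scale, had 92.8%. Olfr1270 had 0 counts in blastocyst wells and was at least 299-fold lower, with an overlap of 9.06% and 3.98% of its stretches shared. Ribosomal protein genes with a pseudogene named after them had a median log2 fold change of 2.75 (61 genes), and those with none so named had 0.66 (23 genes). Rps6 rose from 27.6 to 3162 CPM and Gapdh, which is used in every cell, from 1.97 to 238 CPM, and both have annotated pseudogenes. Values of genes with such overlaps or copies are uncertain, since stage and counting cannot be separated in them. The count of 3993 fell to 2513 with DESeq2 and to 2586 or 2596 without morula replicate 1 or 2.

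In the NKX1-2 wells, 4690 of 10221 genes differed between the stages by edgeR, 2242 higher and 2448 lower in the blastocyst. The same list of trophectoderm genes had 10 of 21 genes higher and 4 lower (camera, adjusted p = 0.0200), and the p53 target list 16 of 31 higher and 5 lower (adjusted p = 0.0159). Of the 33 lists, 13 passed and 0 did so with an estimated correlation, where the lowest adjusted p was 0.425, against 14 at an unadjusted camera p under 0.05 and 18 by fry. The count of 4690 fell to 2998 with DESeq2 and to 2266 without blastocyst replicate 1.

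Wells of the NKX1-2 morpholino were deeper than control wells of the same plate. The median total count, averaged over the 4 plates, was 34612 in control wells and 40771 in NKX1-2 wells, a mean difference of 6158 ± 2148 (SD, n = 4 plates), and NKX1-2 wells were higher in 4 of 4 plates. The median number of detected genes was 5824 and 6246, a difference of 421.9 ± 249.4, higher in 4 of 4 plates. The mitochondrially encoded share was 5.49% in control and 5.02% in NKX1-2 wells, a difference of -0.473 ± 0.282 percentage points. In the exact sign-flip test, two-sided, p = 0.13 for each measure, the smallest value that 4 plates allow. The 177 blastocyst wells kept formed 9 clusters, of which 1 had 3 of the fixed lineage markers among its top 10 genes, the trophectoderm markers Krt18, Lrp2 and Krt8. The other clusters could not be named, so no shares of cell types were compared. Several clusters followed plate and morpholino. The named cluster held 21 and 5 NKX1-2 wells and 0 and 3 control wells of replicates 1 and 2. A cluster of 35 wells held 10 and 24 NKX1-2 wells and 1 and 0 control wells. All 16 wells of 1 cluster were control wells of replicate 1, and all 14 wells of another were control wells of replicate 2. A cluster of 22 wells held both morpholinos in both replicates.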

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

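The comparisons in female wells, with the highest well left out and, for gene lists, in thinned wells were chosen after the data were seen. Apoa1 stood out because its effect differed between the stages (difference -4.22 on the log2 scale), higher in both morula plates and lower in both blastocyst plates. The gene model 4930500L23Rik differed by 2.25, with log2 fold changes of 0.09 and -0.04 in the morula plates and of 1.77 and 2.45 in the blastocyst plates. It was lost with DESeq2, voom, every well, thinned wells, female wells and no plate block, and without morula replicate 2. For 3 gene lists the test of the difference itself passed with the preset correlation. It did not pass by fry or with an estimated correlation, which leaves few degrees of freedom. The median difference was -0.34 for p53 targets, 0.19 for nuclear oxidative phosphorylation and 0.14 for the proteasome. Apoa1 lay between -5.65 and -3.86 over 15 alternative settings. In female wells its difference was -5.65 and did not pass, with fewer counts. There, the nuclear oxidative phosphorylation list passed, and the p53 target and proteasome lists did not. All 3 lists passed with thinned wells and with the highest well of each gene left out. The share of female wells stays open for the p53 target and proteasome lists, since female wells hold fewer counts.

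The genes changed on average over both stages were weighed against explanations other than the morpholino. In a model with the plate and 1 effect for all 8 sums, which is not the model behind the 315 genes, the real split called 213 genes. It was the 1 of 32 fitted splits of the sums into 4 and 4 with as many, and the highest other called 3. Only 8 of these splits part the sums of every plate, as the real one does, and 8 are too few for a share under 0.05. Between 24 and 24 barcodes of the same morpholino the median number of genes called was 2.56% of that between the morpholinos (3 and 2.5 against 117), which argues against single barcode sequences, while a property shared by every barcode of a morpholino stays open. In female wells the median size of the called changes was 95.7% of that in all wells, and 303 of 304 genes kept their direction. This argues against the share of female wells, although many wells of blastocyst replicate 2 had both Xist and Y-linked counts. Depth stays open in part, since NKX1-2 wells were deeper in 4 of 4 plates. With deep wells thinned to the plate median, 291 genes passed, against 315. The mix of blastocyst clusters, which differed between the morpholinos, was not weighed.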

How the results depend on the processing

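Female wells, the highest well left out, autosomes and protein-coding genes were settings chosen after the data were seen, as were every well and thinned wells for the gene lists. Counts of genes are given for morula, blastocyst, average, difference, stages in control wells and stages in NKX1-2 wells, where 60, 79, 315, 2, 3993 and 4690 genes passed. DESeq2 called 15, 21, 60, 1, 2513 and 2998. No filter on low counts gave 179, 254, 532 and 27 in the first 4. With no replicate block, the counts were 34, 43, 185 and 1. The difference had 1 gene with every well, with thinned wells and with voom. Leaving out 1 plate, where the lone sums of a stage are assumed to vary like the others, gave 13 to 838, 99 to 635, 92 to 1071, 4 to 252, 2586 to 4213 and 2266 to 3592. Fits of only the plates of the stage called 834 and 123. Female wells gave 8, 14, 36, 0, 1602 and 2684 by edgeR. For the difference, 336 genes had an unadjusted p under 0.05 by edgeR in female wells, against 699 in all wells. Of the gene lists, 1, 6, 1, 3, 13 and 13 passed by camera, and 0 did with an estimated correlation in each comparison (5, 11, 9, 7, 16 and 14 at an unadjusted camera p under 0.05). By fry, 0 passed for the morula, the blastocyst and the difference. Female wells gave 0, 3 and 0 lists in the first 3, and thinned wells 2 for the average. Without 1 plate, 0 to 4, 9 to 12, 0 to 7 and 2 to 8 lists passed. Of 4677 values of named genes under an alternative, 4142 kept their direction and side of the threshold, 471 no longer passed, 62 newly passed and 2 reversed. Omt2b was reversed at -0.002 on average in female wells, and Olfr1109 at -1.08 in the morula with its highest well left out. Of the 471, 122 were in female wells and 96 with DESeq2. The Nkx1-2 level was 0 under every setting. The cause was not tested. Female wells and left-out plates hold fewer counts by construction, which would not raise the number of genes called. More genes passed without a blastocyst plate and with only the plates of the stage. The main fit shares 1 spread per gene between the stages. Log2 fold changes per plate correlated at 0.327 between the morula plates and at 0.120 between the blastocyst plates. Between plates of different stages they correlated at 0.141 to 0.206, so the blastocyst plates were the pair least alike.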

Other observations

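The test of overlap on the opposite strand was chosen only after the result was seen. X-linked genes lay higher with the NKX1-2 morpholino in blastocyst wells, by 0.243 on the log2 scale over autosomal genes (95% interval 0.174 to 0.316, 273 X-linked genes). Intervals in this section came from 2000 resamplings of the genes and hold no spread between plates or embryos. In female wells alone the difference was -0.0238 (interval -0.0748 to 0.0272), so the different share of female wells may account for it. The morula difference was -0.0971 in all wells and 0.00208 in female wells.

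Wells of 1 plate and morpholino may come from few embryos. With X-linked and Y-linked genes left out, 81.0% of the 3 nearest wells of a well had its sex class, against 60.6% after permutation (p = 0.0002, two-sided, the smallest the permutations can give, 267 wells). Within a plate and morpholino, the permutation p was 0.28 for control wells of morula replicate 1. For control and NKX1-2 wells of blastocyst replicate 2 it was 0.11 and 0.82, and in the other groups it was at most 0.0022. An effect of sex on autosomal genes stays open, and if wells share embryos, the number of embryos per sum is smaller than the number of wells.

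The large stage differences may in part come from how the matrices of both stages were counted. Genes with at least 50% of their exonic length on the opposite strand of another gene's exons were more often over 8-fold higher in the blastocyst, with an odds ratio of 32.3 (Fisher's exact test, two-sided, p = 1.81e-22, 60 against 5451 genes). Reads shared with pseudogene copies stay open and cannot be told apart from stage. Processed pseudogenes had a median of -0.63, with 128 of 1017 called higher in the blastocyst and 390 lower. Protein-coding genes had a median of 0.05, with 1712 of 8052 called higher and 1514 lower. Genes outside the ribosomal protein list with a pseudogene named after them lay 0.219 higher than those with none so named (interval 0.0997 to 0.389, permutation p = 0.0075). Genes with much shared sequence lay 0.147 higher (interval -0.0005 to 0.326, permutation p = 0.122). Mitochondrial genes of the light strand had a median of -3.90 (7 genes) and those of the heavy strand one of -0.28 (15 genes).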
